A study of Mus musculus with 25 samples.

How the data were processed

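Lung RNA of 25 female mice was measured, 13 WT and 12 FP-KO, on Day 0, Day 7 and Day 14 after bleomycin. Per the labels' protocols, mice received bleomycin at 1 mg/kg in 40 ul of saline into the trachea on Day 0, total RNA was taken from lung with Sepasol, and 6 ug was used to make biotin-labelled cRNA for Affymetrix mouse genome arrays. Groups and mouse numbers were taken from the sample titles, and each array is taken as 1 mouse, as titled. The deposited table gives 1 linear intensity per probe set and array, for 45101 probe sets, from 0 to 51673.8. In these values every array has a trimmed mean of 500 (2% left out at each end), so the authors scaled each array to 500, and the software is not given in the sources used here. The number of arrays, 4 or 5 per group, sets the precision.

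Rules for processing, lists, tests, named genes and most alternatives were set before the data were examined. Intensities were floored at 24.3, the 20th percentile of all values, and taken to log2. The array medians on that scale ran from 6.81 to 7.24, a range of 0.432 that is above the limit of 0.3, so the arrays were quantile-normalized. Left out of the gene tests were 64 control probe sets, 932 with several symbols and 9160 without a symbol in the tables used here. Of the 34958 probe sets with 1 symbol, 34754 had a symbol matched by gene number to the reference gene table (GRCm38.p6, used for names and neighbours only), 204 did not match and 0 were renamed. The probe set with the highest mean stood for a gene (18193 genes). A gene was tested when it lay above the array median in at least 4 arrays, which left 12062. Probe sets without a symbol were tested apart.

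Tests were run in R 4.3.3 with limma 3.58.1 (lmFit on 6 group means, contrasts.fit, eBayes), and figures were drawn with python 3.11.15 and matplotlib 3.10.9. The 9 contrasts are Day 7 and Day 14 against Day 0 in each genotype, FP-KO against WT on each of the 3 days, and the interaction of genotype and time at Day 7 and Day 14. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a second count asks for a log2 change of at least 1. For the comparisons of 2 groups the number of genes without overlap between them was also counted. No covariate was used. All 25 arrays share 1 estimate of spread per gene.

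There were 35 gene lists: collagens, other matrix, proteases, contractile, TGF-beta, p53, cell cycle, macrophage, alternative activation, neutrophil, eosinophil with mast cell and basophil, dendritic cell with MHC class II, T cell, NK and cytotoxic, B cell, plasma cell, interferon-stimulated, cytokine, acute-phase, prostanoid, alveolar type 1, alveolar type 2, club and goblet, ciliated, endothelial, resident fibroblast, adipocyte, erythroid, cardiac and skeletal muscle, thymocyte, clock, immediate-early and heat-shock, glucocorticoid-responsive with metallothionein, sterol and fatty acid synthesis, and NRF2. Camera from limma tested 33 of them in each contrast with a preset correlation between genes of 0.01, two-sided. The erythroid and thymocyte lists have fewer than 3 measured genes and were left out of camera. An adjusted p over the list alone was also computed for each member. As a test with the mouse as the unit, the mean log2 intensity of a list in each mouse was compared between genotypes on each day by an exact permutation test, two-sided, with Benjamini-Hochberg adjustment over 99 tests. The smallest p it can give is 0.0286 for 4 mice against 4 and 0.00794 for 4 against 5.

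Time courses were compared across genes, which are not independent replicates, by Pearson and Spearman correlation over the 12062 genes. A slope of the FP-KO change on the WT change was taken over genes that passed on the mean change of both genotypes, with a 95% interval from 1000 resamples of mice within groups. Genes within 20 Mb of Ptgfr were compared with the rest by Fisher's exact test, two-sided. Named genes were Ptgfr, then for each time contrast the 8 that rose and the 6 that fell most among genes that passed without overlap between groups. For genotype contrasts and interactions they were up to 8 each way among genes that passed, or the 5 smallest p where fewer than 5 passed, and for each list up to 4 members that passed. Genes with a clone-type symbol keep their place and are not described.

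Whether equal mouse numbers pair the samples was checked in the data, as the labels name no pairs. Deviations from the group means correlated between FP-KO and WT mice of equal number at 0.119 to 0.345 on Day 0 and 0.141 to 0.221 on Day 7, and at -0.308 to 0.437 on Day 14. The mouse number was therefore also tried as a block, and list means per mouse on Day 0 and Day 7 were also tested within pairs of equal number by an exact permutation test, whose smallest two-sided p is 0.125. Alternatives were the values as deposited, a common median, other floors and filters, the mean of all probe sets, trend and robust eBayes, array weights, the replicate block, an estimated correlation, only the groups of a comparison, windows of 10 and 40 Mb, and each mouse left out. Blocks and fits for the sets of Day 14 samples, a total least squares slope, the region test without Ifi44l, the prostanoid list without Ptgfr and the test of list means within pairs were added after the data were seen. The block for the sets of Day 14 samples also parted the Day 0 and Day 7 mice No. 1 and 2 from No. 3 and 4, with 1 shift for all days.

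The steps were tested on simulated data made from the spread of these arrays, with 12062 genes. For WT Day 7 against Day 0, 44.8%, 97% and 100% of genes changed by log2 0.5, 1 and 2 were recovered. For FP-KO against WT at Day 14 the shares were 50.7%, 92.5% and 98.5%, and for the Day 14 interaction 22.4%, 74.6% and 95.5%. Unchanged simulated genes that passed numbered 12, 11 and 5 in these comparisons, and camera called 2 of 2 shifted lists and 0 of the others. The simulated genes were drawn independently of each other, without the sets of Day 14 samples. The run therefore cannot show how camera's preset correlation serves genes that move together.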

Results

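The lungs of 25 female mice were measured, each on 1 Affymetrix mouse genome array, which reads most mouse transcripts as the intensity of probe sets (groups of short DNA probes for 1 transcript). Of these mice 13 were wild type (WT) and 12 were knockouts of FP (FP-KO), the receptor for prostaglandin F2α, encoded by Ptgfr. Bleomycin, an anticancer drug that injures the lung and leads to fibrosis, was given into the windpipe on Day 0. WT lungs were taken on Day 0 (n = 4), Day 7 (n = 4) and Day 14 (n = 5), and FP-KO lungs on the same days (n = 4 on each). The series asks how expression changes over time in FP-KO lungs beside WT lungs. In the deposited values each array has a trimmed mean intensity of 500, and the array medians run from 112.3 to 151.5. The number of arrays limits the precision of every value given here. Changes are log2 differences with the standard error of the limma fit after ±, and a gene rose, fell or passed where its adjusted p over the 12062 genes tested was under 0.05.

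On the first principal component, which holds 42.0% of the variance between arrays, the Day 0 lungs of both genotypes lie between -35.0 and -24.8. The WT Day 14 lungs lie between 13.4 and 25.5. Mice No. 1, 3 and 4 of FP-KO Day 14 lie between -5.36 and 1.45, and No. 2 lies at -28.9, among the Day 0 arrays. The array of FP-KO Day 14 No. 2 also has the highest 18S ribosomal RNA intensity of its group, 6339 against a median of 315.5 over all arrays, and an Actb 3′ to 5′ intensity ratio of 1.56 against 1.38 to 1.40 in the rest of its group. In the Day 0 arrays this ratio runs from 1.32 to 1.62, and FP-KO Day 0 No. 1, with 18S at 6648 and a ratio of 1.55, lies with its group at -25.4. On the second component, 16.9% of the variance, WT Day 14 No. 1 to 3 and FP-KO Day 14 No. 1 and 2 stand apart from WT Day 14 No. 4 and 5 and FP-KO Day 14 No. 3 and 4. The first of these sets lies between 27.6 and 30.0, the second between -2.28 and 1.35 and the Day 0 arrays between -7.97 and -2.48. What sets them apart is not in the sources used here. Day 14 against Day 0 in either genotype thus holds this difference as well as the time after bleomycin. Both sets of Day 14 samples hold both genotypes, so the Day 14 genotype differences of several gene lists are also given within each set.

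**Figure D1:**
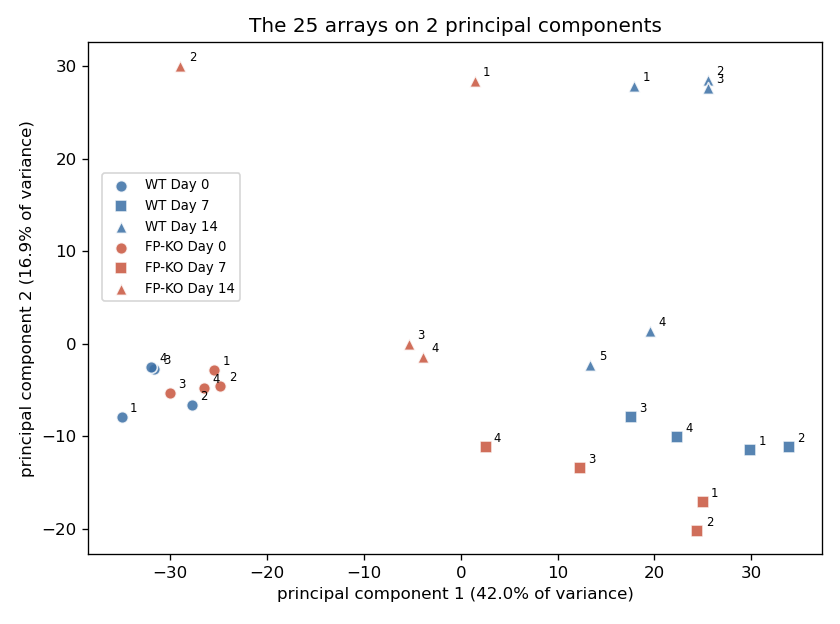
Each point is 1 array, placed by its scores on principal components 1 (horizontal, 42.0% of variance) and 2 (vertical, 16.9% of variance), with colour for genotype, shape for day and the mouse number beside it. FP-KO Day 14 No. 2 lies at -28.9 on component 1, among the Day 0 arrays, and the Day 14 arrays fall into 2 sets on component 2.

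Ptgfr intensity was 305.1 ± 53.8 (SD, n = 4) in WT lungs on Day 0, 173.9 ± 45.5 (SD, n = 4) on Day 7 and 184.0 ± 45.9 (SD, n = 5) on Day 14. In FP-KO lungs it was 43.6 ± 15.0, 44.0 ± 4.38 and 32.3 ± 11.04 on the same days (SD, n = 4 each). The lowest WT array, at 127.3, lay above the highest FP-KO array, at 59.0, and 1 FP-KO Day 14 array was under the floor. The array holds other Ptgfr probe sets, of which 1 was different in FP-KO lungs by log2 -3.29 on Day 0, -2.69 on Day 7 and -2.56 on Day 14, with 2, 2 and 1 of 4 FP-KO arrays at the floor. Another differed by -2.56, -1.39 and -1.46, which are bounds, as 4, 3 and 4 of 4 FP-KO arrays were at the floor, so that it was lower by at least as much. A further one differed by -2.07, -1.25 and -1.54 (0, 1 and 0 arrays at the floor), of which the Day 7 value did not pass (adjusted p = 0.175). The last differed by -0.89, -0.84 and -0.74 with 1, 2 and 2 of 4 FP-KO arrays at the floor and did not pass on any of the 3 days (adjusted p = 1, 0.889 and 0.290). Where FP-KO arrays are at the floor, the difference can be larger than the value given. Which of the probes lie in the deleted part of the gene is not given in the sources used here.

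**Figure D2:**
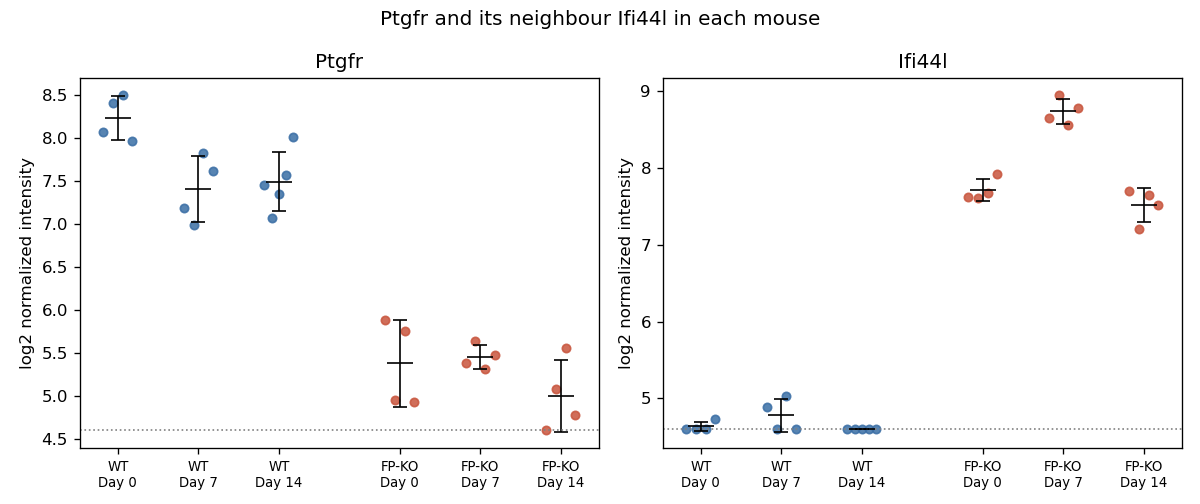
Log2 normalized intensity (vertical) of Ptgfr (left) and of its chromosomal neighbour Ifi44l (right) in each mouse of the 6 groups, with bars for the group mean ± SD and a dotted line for the intensity floor of 24.3. Ptgfr separates the genotypes without overlap (lowest WT array 127.3, highest FP-KO array 59.0), and Ifi44l is at or near the floor in WT lungs and above it in FP-KO lungs.

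The first comparison asks how WT lungs change by 7 days after bleomycin. Ptgfr fell by 0.83 on the log2 scale (adjusted p = 0.00884). Among the largest rises were the cell adhesion molecule Chl1 (4.65 ± 0.37), the lipid-sensing macrophage receptor Trem2 (4.32 ± 0.53), the squamous envelope protein Sprr1a (4.19 ± 0.42) and the matrix glycoprotein tenascin C, encoded by Tnc (4.05 ± 0.39). The protease inhibitor Timp1 (4.01 ± 0.28), the acute-phase protein Saa3 (3.98 ± 0.38), arginase 1, Arg1 (3.76 ± 0.53), and the macrophage elastase Mmp12 (3.70 ± 0.55) completed the 8 named rises. The fatty acid carrier Fabp1 (-2.59), the growth factor carrier Igfbp3 (-2.30), the matrix protein Ecm2 (-2.02), the glutamate receptor subunit Gria1 (-1.98) and the lectin receptor Asgr1 (-1.98) fell most. In all, 4238 genes passed, 2066 up and 2172 down, of which 490 rose and 196 fell by at least 1 on the log2 scale. The 2 groups did not overlap in 4225 genes, 35.0% of those tested, where chance gives such a gap in 2.86%.

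Of 16 collagen and collagen-processing genes 13 rose in WT lungs by Day 7 and 3 did not pass (13 up adjusted over the list alone), with the prolyl hydroxylase P4ha3 at 2.42 ± 0.29 and the collagen chains Col1a1 at 2.26 ± 0.25 and Col5a2 at 2.19 ± 0.22. Of 19 other matrix genes 18 rose (18 adjusted over the list alone), among them elastin, Eln (3.16 ± 0.38), and versican, Vcan (2.12 ± 0.26). The camera test placed both lists above other genes (adjusted p = 2.7e-08 and 2.13e-13), with adjusted p = 0.069 and adjusted p = 0.0664 with an estimated correlation. Of 12 matrix-degrading proteases 10 rose (10 up and 2 down adjusted over the list alone), such as Adamts4 (2.40), Mmp8 (2.17) and Mmp13 (2.04). Of 12 TGF-beta ligands, receptors and targets 8 rose and 1 fell, the same counts adjusted over the list alone, including the activin chain Inhba (1.91 ± 0.51), Tgfbi (1.41), Pmepa1 (1.03) and the matricellular Ccn2 (0.98). Of 11 smooth muscle and myofibroblast contractile genes 2 fell and the rest did not pass (1 down adjusted over the list alone), the 2 being Synpo2 (-0.70) and Cnn1 (-0.33). Of 14 p53 targets 10 rose (10 adjusted over the list alone), with the death receptor Eda2r at 2.10 ± 0.26 and the cell cycle inhibitor Cdkn1a at 2.09 ± 0.31. Of 26 cell cycle genes 24 rose (24 adjusted over the list alone), led by the mitotic kinase Cdk1 (2.97 ± 0.31) and the proliferation marker Mki67 (2.54 ± 0.24).

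Immune genes moved apart by cell type in WT lungs on Day 7. Of 18 macrophage markers 17 rose (17 adjusted over the list alone), such as the scavenger receptor Msr1 (2.79 ± 0.26), the complement chain C1qb (2.70 ± 0.27) and Gpnmb (2.52 ± 0.38). Alternative activation genes rose in 8 of 11 (8 adjusted over the list alone), including Retnla (2.61) and the chemokine Ccl17 (2.47). Dendritic cell and MHC class II genes rose in 9 of 12 (9 adjusted over the list alone), for example Itgae (1.55) and the costimulator Cd86 (1.46). NK and cytotoxic cell markers fell in 5 of 8 (6 adjusted over the list alone), with granzyme A, Gzma, at -1.33 ± 0.23 and the NK receptor Ncr1 at -1.14. B cell markers fell in 5 of 9 (7 adjusted over the list alone), for example the receptor chain Cd79b (-0.97). Of 12 T cell markers the costimulator Icos rose (1.16) while Cd2 (-0.63) and Cd8b1 (-0.58) fell (1 up and 2 down adjusted over the list alone). Of 9 plasma cell and immunoglobulin genes the IgA chain Igha rose (1.22) and the plasma cell regulator Prdm1 fell (-0.91), and 0 up and 1 down passed adjusted over the list alone. Cytokines and chemokines rose in 13 of 20 (14 up and 2 down adjusted over the list alone), led by the monocyte attractants Ccl2 (3.55 ± 0.30) and Ccl7 (3.14 ± 0.36) and by Il6 (2.73 ± 0.37). Interferon-stimulated genes rose in 11 of 17 (11 adjusted over the list alone), with the chemokines Cxcl9 at 3.60 ± 0.47 and Cxcl10 at 3.14 ± 0.26. Acute-phase and complement genes rose in 6 of 9 (6 adjusted over the list alone), among them Serpina3n (2.42) and lipocalin 2, Lcn2 (1.87). Of 19 prostanoid genes 8 rose and 4 fell (9 up and 4 down adjusted over the list alone), with the prostaglandin E2 receptor Ptger4 at 1.55 ± 0.15 and cyclooxygenase 2, Ptgs2, at 0.95 ± 0.13.

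Endothelial markers fell in 14 of 22 in WT lungs by Day 7 (17 adjusted over the list alone), such as the endothelin receptor Ednrb (-1.20 ± 0.16) and the VEGF receptor Kdr (-0.85). Resident fibroblast markers fell in 6 of 9 (6 adjusted over the list alone), including Inmt (-0.92) and the integrin Itga8 (-0.86). Alveolar type 1 markers fell in 6 of 10 (2 up and 6 down adjusted over the list alone), with Akap5 at -0.80 while Igfbp2 rose (0.62). Alveolar type 2 markers fell in 5 of 11 (6 adjusted over the list alone), for example the transcription factor Etv5 (-0.85). Club and goblet cell markers fell in 7 of 12 (2 up and 7 down adjusted over the list alone), such as Bpifa1 (-1.14), while Agr2 rose (0.86). Ciliated cell markers fell in 6 of 12 (7 adjusted over the list alone), including Tppp3 (-1.23) and Hydin (-0.91). Adipocyte markers fell in 6 of 7 (7 adjusted over the list alone), among them adiponectin, Adipoq (-1.66), and cardiac and skeletal muscle genes fell in 10 of 12 (11 adjusted over the list alone), among them myoglobin, Mb (-1.52). Of 2 erythroid genes the haem enzyme Alas2 fell (-1.71; 2 down adjusted over the list alone), and neutrophil (6 measured), eosinophil, mast cell and basophil (3) and thymocyte (1) genes did not pass. Circadian clock genes fell in 7 of 14 (2 up and 8 down adjusted over the list alone), with Dbp at -1.35 and Nr1d1 at -1.35. The metallothioneins Mt2 (2.13) and Mt1 (1.32) rose among 8 glucocorticoid-responsive and metallothionein genes (3 up and 1 down; 3 and 1 adjusted over the list alone), as did the stress factor Atf3 (0.93) among 11 immediate-early and heat-shock genes (2 up and 1 down; 2 and 1 adjusted over the list alone). Haem oxygenase, Hmox1, rose (1.36) and the glutathione transferase Gstm1 fell (-1.34) among 9 NRF2 targets (3 up and 3 down; 5 and 3 adjusted over the list alone). Of 13 sterol and fatty acid synthesis genes 2 fell (2 adjusted over the list alone), Acly (-0.36) and Scd2 (-0.30). With camera's preset correlation 24 of 33 lists passed in this comparison, 13 up and 11 down. With an estimated correlation camera called 0 lists at an adjusted p under 0.05 and 14 at an unadjusted p under 0.05.

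The WT lungs of Day 14 were set against the same Day 0 mice. Ptgfr fell by 0.75 on the log2 scale (standard error 0.23, adjusted p = 0.0119). The named rises were Trem2 (4.23 ± 0.50), Mmp12 (4.19 ± 0.52), Eln (3.89 ± 0.36), Tnc (3.75 ± 0.37), Chl1 (3.53 ± 0.35), the matricellular Thbs4 (3.19 ± 0.33), the Schlafen family member Slfn9 (3.16 ± 0.36) and the growth factor epiregulin, Ereg (2.96 ± 0.35). Fabp1 (-2.94) and Asgr1 (-2.33) fell most together with genes of fat and muscle: the cytochrome oxidase subunit Cox8b (-2.94), Adipoq (-2.56 ± 0.34), the lipid synthesis regulator Thrsp (-2.37) and the atrial peptide Nppa (-2.34 ± 0.36). In all, 4664 genes passed, 2306 up and 2358 down, of which 487 rose and 214 fell by at least 1 on the log2 scale. The sets of Day 14 samples enter this count, and fewer genes passed with WT No. 4 and 5 alone at Day 14, with fewer arrays. No overlap between the groups was seen in 3438 genes, 28.5% of those tested against 1.59% by chance.

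Collagen genes rose in 12 of 16 and fell in 1 in WT lungs at Day 14 (13 up and 1 down adjusted over the list alone), with Col1a1 at 2.93 ± 0.23, P4ha3 at 2.50 and Col5a3 at 1.88. Other matrix genes rose in 19 of 19 (19 adjusted over the list alone), among them Timp1 (2.82 ± 0.26) and the latent TGF-beta binding protein Ltbp2 (2.21). Camera gave adjusted p = 2.06e-09 and 4.29e-16 for these lists, and adjusted p = 0.0994 with an estimated correlation for both. Proteases rose in 9 of 12 and fell in 2 (10 and 2 adjusted over the list alone), such as Mmp13 (2.24) and the gelatinase Mmp2 (2.05). TGF-beta list genes rose in 8 of 12 and fell in 1, with the same counts adjusted over the list alone, including the ligands Tgfb3 (0.91) and Tgfb1 (0.83). Among 11 contractile genes smoothelin, Smtn, rose (0.61) while 2 fell, one being Synpo2 (-0.84), and 1 up and 2 down passed adjusted over the list alone. Cell cycle genes rose in 23 of 26 (25 adjusted over the list alone), with Cdk1 at 2.55 ± 0.30 and Mki67 at 2.39 ± 0.22. The p53 targets rose in 9 of 14 and fell in 2 (10 and 2 adjusted over the list alone), with Cdkn1a at 2.14.

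Macrophage markers rose in 16 of 18 in WT lungs at Day 14 (16 adjusted over the list alone), including Gpnmb (2.74) and C1qb (2.63). The immunoglobulin chain Igha (2.41 ± 0.45) and the joining chain Jchain (2.06 ± 0.54) rose among 9 plasma cell genes (2 up and 1 down; 3 and 1 adjusted over the list alone). NK and cytotoxic markers fell in 8 of 8, the same adjusted over the list alone, with Gzma at -1.76 ± 0.22. Neutrophil markers fell in 4 of 6 (4 adjusted over the list alone), for example the calprotectin chain S100a9 (-1.51), and the mast cell chymase Cma1 fell (-0.84) as the 1 of 3 eosinophil, mast cell and basophil markers that also passed adjusted over the list alone. Icos rose (1.23) while 5 of 12 T cell markers fell, such as Cd8a (-0.98), and B cell markers fell in 6 of 9, with the same T and B cell counts adjusted over the list alone. Cytokines rose in 10 of 20 and fell in 2 (11 and 2 adjusted over the list alone), including Ccl9 (2.36) and Ccl8 (2.36). Interferon-stimulated genes rose in 11 of 17 and fell in 1, with the same counts adjusted over the list alone, Cxcl9 being at 2.27. Alternative activation (7 of 11, 8 adjusted over the list alone), dendritic cell (10 of 12, 10 adjusted over the list alone) and acute-phase genes (7 of 9, 7 adjusted over the list alone) also rose, with Arg1 at 2.54, Cd86 at 1.01 and Saa3 at 2.95. Prostanoid genes rose in 9 of 19 and fell in 2 (11 and 3 adjusted over the list alone), with the prostaglandin E synthase Ptges at 0.75.

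Muscle genes fell in 11 of 12 (11 adjusted over the list alone) and adipocyte markers in 7 of 7, the same adjusted over the list alone, in WT lungs at Day 14, with Mb at -1.95 and the gluconeogenic enzyme Pck1 at -2.16. Ciliated (8 of 12 down, 9 adjusted over the list alone) and club cell markers (8 of 12 down, the same adjusted over the list alone) fell, for example Dynlrb2 (-0.86) and the claudin Cldn10 (-1.25). Endothelial markers fell in 10 and rose in 2 of 22, and resident fibroblast markers fell in 7 and rose in 1 of 9, both with the same counts adjusted over the list alone. Ednrb (-1.40) and Inmt (-0.87) were among those that fell, and the proteoglycan Gpc3 rose (0.59). Type 1 markers went both ways (4 up, 2 down of 10), with Igfbp2 at 1.30, and 3 of 11 type 2 markers rose, among them Muc1 (0.66), again with the same counts adjusted over the list alone. Clock genes fell in 7 of 14 and rose in 1 (8 and 1 adjusted over the list alone), with the output regulator Hlf at -1.21. Junb (0.94), Mt2 (1.51), Hmox1 (1.41) and the desaturase Scd1 (0.53) rose in the immediate-early, metallothionein, NRF2 and lipid synthesis lists. As whole lists these moved less, with medians of 0.05, 0.20, 0.03 and -0.13 in the same order. Camera's preset correlation gave 22 of 33 lists, 13 up and 9 down, whereas with an estimated correlation camera called 0 and 15 at an unadjusted p under 0.05.

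The next comparison asks how FP-KO lungs change by Day 7 from their own Day 0 lungs. Ptgfr, low in FP-KO lungs on each of the 3 days, differed by 0.07 (adjusted p = 0.854), and the difference was -0.03 on the values as deposited and -0.27 with the mean of its probe sets. The named rises were in Trem2 (4.41 ± 0.53), Saa3 (4.04 ± 0.38), Chl1 (3.79 ± 0.37), Sprr1a (3.72 ± 0.42), Ccl2 (3.33 ± 0.30), Timp1 (3.23 ± 0.28), Tnc (3.08 ± 0.39) and Cxcl9 (3.07 ± 0.47). The small GTPase Rasd2 (-1.88), Igfbp3 (-1.72), the ankyrin repeat gene Ankrd63 (-1.63), the transcription factor Gata3 (-1.36) and Fabp1 (-1.35) fell. In all, 2813 genes passed, 1523 up and 1290 down, and 321 rose and 38 fell by at least 1 on the log2 scale. Of the genes tested 3194 showed no overlap between the groups, or 26.5% where chance gives 2.86%. Without FP-KO Day 7 No. 1 the count was 1866. With every array set to a common median, 1467 genes rose and 599 fell, a rise in 71.0% of those that passed against 54.1% with quantile normalization.

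Collagen genes rose in 10 of 16, the same adjusted over the list alone, in FP-KO lungs at Day 7, including Col5a2 (1.52 ± 0.22) and P4ha3 (1.49). Other matrix genes rose in 13 of 19 (16 adjusted over the list alone), such as Eln (1.81 ± 0.38) and Vcan (1.87), and 9 of 12 proteases rose and 1 fell (10 and 2 adjusted over the list alone), with Mmp12 at 2.47 ± 0.55. Cell cycle genes rose in 24 of 26 (25 adjusted over the list alone), with Cdk1 at 2.48 ± 0.31 and the mitotic kinesin Kif20a at 2.33. Macrophage markers rose in 16 of 18, the same adjusted over the list alone, among them Gpnmb (2.02) and Msr1 (2.04). For the matrix, cell cycle and macrophage lists camera gave adjusted p = 4.69e-10, 7.93e-22 and 1.95e-11, and adjusted p = 0.0939 with an estimated correlation for each of the 3. The p53 targets rose in 8 of 14 (9 adjusted over the list alone), led by Cdkn1a (1.98), and 3 of 12 TGF-beta genes rose and 1 fell, the same adjusted over the list alone, with Tgfbi at 1.14 and the inhibitor Smad7 at -0.42. Interferon-stimulated genes (12 of 17) and cytokines (12 of 20, with 1 down) rose, with the same counts adjusted over the list alone, including Cxcl10 (2.88 ± 0.26) and Ccl7 (2.73). Of the T cell markers 3 of 12 rose, the same adjusted over the list alone, among them the checkpoint receptor Ctla4 (1.10), while NK markers fell in 3 of 8 (5 adjusted over the list alone), with Gzma at -0.95. Prostanoid genes rose in 8 and fell in 2 of 19 (9 and 2 adjusted over the list alone), with Ptges at 1.00. Endothelial markers fell in 12 of 22 (15 adjusted over the list alone), for example Kdr (-0.86) and the angiopoietin receptor Tek (-0.78), and clock genes in 9 of 14, the same adjusted over the list alone, with Nr1d1 at -1.16. Of 7 adipocyte markers and 12 muscle genes 0 passed in limma in FP-KO lungs at Day 7, as 0 did adjusted over each list alone. In camera the preset correlation called 20 of 33 lists, 13 up and 7 down, whereas with an estimated correlation camera called 0 and 13 at an unadjusted p under 0.05.

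FP-KO lungs at Day 14 were set against the same FP-KO Day 0 mice. Ptgfr differed by -0.38 ± 0.24 (adjusted p = 0.4). Trem2 (3.05 ± 0.53, adjusted p = 0.00426), Eln (2.06 ± 0.38, adjusted p = 0.0057), Cdkn1a (1.47 ± 0.31), the C1q-related C1qtnf6 (1.32), insulin-like growth factor 1, Igf1 (1.29), Col1a1 (1.25 ± 0.25, adjusted p = 0.00836) and the protease inhibitor A2m (1.21) rose most. The calprotectin chains S100a9 (-2.08 ± 0.38) and S100a8 (-1.72 ± 0.35), the myeloid membrane protein Ifitm6 (-1.78), the lymphocyte regulator Eomes (-1.61 ± 0.30), Gzma (-1.41 ± 0.23) and the platelet glycoprotein Gp9 (-1.32) fell. In all, 393 genes passed, 223 up and 170 down, with 36 up and 27 down by at least 1 on the log2 scale. The sets of Day 14 samples enter this count too. Groups without overlap were seen in 1190 of the genes tested, 9.87% against 2.86% by chance. The count was 101 without FP-KO Day 14 No. 1, 156 and 212 without FP-KO Day 0 No. 2 and No. 4, and 569 without FP-KO Day 14 No. 2. With a common median 166 passed, 113 up and 53 down (68.1% up against 56.7%), and 0 passed when limma was fitted to these 2 groups only, where 1921 had an unadjusted p under 0.05.

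Other matrix genes rose in 10 of 19 in FP-KO lungs at Day 14 (15 adjusted over the list alone), with Tnc at 1.47 ± 0.39, the microfibril protein Mfap4 at 1.05 and Ltbp2 at 1.01. Camera gave this list adjusted p = 8.07e-14, and adjusted p = 0.0764 with an estimated correlation. Collagen genes rose in 6 of 16 (10 adjusted over the list alone), among them P4ha3 (1.16 ± 0.29) and Col1a2 (0.70). Macrophage markers rose in 7 of 18 (12 adjusted over the list alone), such as Gpnmb (1.88) and C1qb (1.18), p53 targets in 6 of 14 (8) and proteases in 4 of 12 (7 up and 1 down), with Mmp12 at 2.09 ± 0.55. NK and cytotoxic markers fell in 5 of 8 (8 adjusted over the list alone), including granzyme B, Gzmb (-1.16), and perforin, Prf1 (-0.91). Camera gave the NK list adjusted p = 5e-11, and adjusted p = 0.0519 with an estimated correlation. Neutrophil (3 of 6), B cell (4 of 9) and T cell markers (3 of 12) also fell, and 3, 4 and 6 did adjusted over the list alone, with Cd79b at -0.85 and Cd8b1 at -0.93. Cell cycle genes did not pass individually: 0 of 26 in limma, 5 up adjusted over the list alone. Ciliated, club, endothelial, adipocyte and muscle genes had 0 members past the threshold in limma at Day 14 in FP-KO lungs, and adjusted over the list alone 1 ciliated marker rose and 0 of the others passed. Of the lists, camera's preset correlation called 16, 11 up and 5 down, whereas with an estimated correlation camera called 0 and 8 at an unadjusted p under 0.05.

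The time courses of both genotypes were then set side by side, each against its own Day 0 mice. At Day 7, 1218 genes rose in both genotypes and 1013 fell in both, where independence would give 260.9 and 232.3, and 0 limma calls went opposite ways. Across the 12062 genes, which are not independent replicates, the Day 7 changes correlated with a Pearson value of 0.874 and a Spearman value of 0.804. At Day 14, 199 genes rose and 139 fell in both (42.6 and 33.2 if independent), with Pearson 0.691 and Spearman 0.646. Mice of both sets of Day 14 samples are in each genotype, so a difference of a set from Day 0 can enter these Day 14 values. Over 5618 genes that passed on the mean change of both genotypes, the FP-KO change at Day 7 had a slope of 0.735 on the WT change (95% interval 0.551 to 0.870, mice resampled). Over 4692 such genes at Day 14 the slope was 0.429 (0.259 to 0.583), and 85.6% of them changed less in FP-KO lungs. Trem2 and Eln follow this pattern, at 4.23 and 3.89 in WT and 3.05 and 2.06 in FP-KO lungs. Without FP-KO Day 14 No. 2 the slope was 0.502 (0.372 to 0.623), and within the sets of Day 14 samples it was 0.478 and 0.506. By total least squares, which allows for noise in both changes, the slopes were 0.768 at Day 7 and 0.461 at Day 14.

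The next question is whether the genotypes differ at Day 0, and the sources used here do not say whether these lungs were taken before or after bleomycin was given. At Day 0 Ptgfr differed in FP-KO lungs by log2 -2.86 ± 0.24 (adjusted p = 1.6e-07), and Ifi44l, an interferon-induced gene 0.04 Mb from Ptgfr, was higher by at least 3.07 ± 0.11 (adjusted p = 6.02e-15), at an intensity of 209.9 ± 22.0 (SD, n = 4) against 11 in WT lungs, of which 3 of 4 were at the floor. A second Ifi44l probe set was higher in FP-KO lungs by at least 3.11, 4.14 and 2.78 on Day 0, Day 7 and Day 14, with all WT arrays at the floor, and the last, at or near the floor in both genotypes, differed by 0.03, 0.17 and 0.14 and did not pass. Ptgfr and Ifi44l were the only genes of 12062 to pass in limma, and 403 had an unadjusted p under 0.05. The groups did not overlap in 255 genes, or 2.11% of those tested, where chance gives 2.86%. The next smallest p values belonged to Gipc2, 0.3 Mb from Ptgfr (-0.76 ± 0.14, adjusted p = 0.0619), the ubiquitin ligase Herc6 (0.49 ± 0.11, adjusted p = 0.392) and Icos (0.69 ± 0.15, adjusted p = 0.392). Interferon-stimulated genes had a positive difference in 17 of 17, median 0.36, with 0 past the threshold in limma and 2 adjusted over the list alone. Camera gave them adjusted p = 9.08e-14, and adjusted p = 0.123 with an estimated correlation. Per mouse, the mean of this list was 9.39 ± 0.14 (SD, n = 4) in FP-KO and 9.05 ± 0.14 (n = 4) in WT lungs, without overlap (exact permutation p = 0.0286, two-sided, adjusted p = 0.118). It was higher in 4 of 4 pairs of equal mouse number, where the exact permutation p within pairs was 0.125, the smallest that 4 pairs allow. Dendritic cell and MHC class II genes (positive in 10 of 12, median 0.25), neutrophil (4 of 6, 0.71), T cell (9 of 12, 0.16), NK (7 of 8, 0.25) and macrophage markers (16 of 18, 0.14) also had positive medians, with 0 past the threshold in limma and 0, 2, 1, 0 and 0 adjusted over the list alone. Camera gave them adjusted p = 9.73e-05, 0.00152, 0.00444, 0.00543 and 0.0146, and adjusted p = 0.334 with an estimated correlation for the first 3, 0.453 and 0.6 for the others. Collagen genes were positive in 14 of 16 (median 0.21, 0 in limma, 0 adjusted over the list alone), with camera at adjusted p = 9.73e-05, and adjusted p = 0.334 with an estimated correlation. Leaving out FP-KO Day 0 No. 1 ended the camera calls of collagen, neutrophil, T cell and NK genes, and leaving out No. 2 those of neutrophil, NK and macrophage genes. The macrophage call also ended without WT Day 0 No. 1 and the NK call without WT Day 0 No. 2. Cardiac and skeletal muscle genes were negative in all 12 (median -0.45) and adipocyte markers had a median of -0.61, with 0 called in limma in either list and 0 adjusted over the list alone. Camera gave these adjusted p = 2.48e-09 and 9.73e-05, and adjusted p = 0.334 with an estimated correlation for both. In all, camera's preset correlation called 13 lists, 10 up and 3 down (5 without FP-KO Day 0 No. 1 and 7 without No. 2), whereas with an estimated correlation it called 0 and 3 at an unadjusted p under 0.05.

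At Day 7 the genotypes differed in the same 2 genes. Ptgfr differed by -1.95 ± 0.24 (adjusted p = 1.9e-04) and Ifi44l was higher by at least 3.95 ± 0.11 (adjusted p = 2.22e-17), at an intensity of 428.1 ± 50.6 (SD, n = 4) against 16.5 in WT lungs (2 of 4 at the floor). In limma 878 genes had an unadjusted p under 0.05, these 2 among them, and 4 passed without FP-KO Day 0 No. 3. No overlap was seen in 652 genes, 5.41% of those tested against 2.86% by chance. The sialyltransferase St6galnac5 (1.25 ± 0.25, adjusted p = 0.108), also near Ptgfr, Prf1 (0.85 ± 0.17, adjusted p = 0.108) and the cadherin Cdh16 (1.15 ± 0.23, adjusted p = 0.108) came next and did not pass. NK and T cell markers were higher without single calls over all genes: 4 of 8 and 3 of 12 passed adjusted over the list alone. Camera gave them adjusted p = 4.28e-06 and 6.21e-06, and adjusted p = 0.15 with an estimated correlation for both. Other matrix genes were lower, 5 of 19 adjusted over the list alone, and collagens had a median of -0.22, with camera at adjusted p = 3.74e-08 and 1.54e-05, and adjusted p = 0.248 with an estimated correlation for both. Per mouse, NK (0.48), T cell (0.39) and collagen (-0.28) means differed without overlap (exact permutation p = 0.0286 each, adjusted p = 0.118). Each differed the same way in 4 of 4 pairs of equal mouse number, where the exact permutation p within pairs was 0.125, the smallest that 4 pairs allow. The prostanoid mean (-0.16) also differed without overlap, but this list holds the deleted gene, and with Ptgfr left out it differed by -0.06 (exact permutation p = 0.371, adjusted p = 0.584). Camera's preset correlation called 16 lists, 6 up and 10 down (8 without WT Day 7 No. 2), whereas with an estimated correlation it called 0 and 6 at an unadjusted p under 0.05.

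The genotypes were also compared at Day 14. Ptgfr differed by -2.49 ± 0.23 (adjusted p = 8.44e-07). Chl1 (-2.51 ± 0.35, adjusted p = 4.27e-04), Thbs4 (-2.10 ± 0.33), the Wnt antagonist Frzb (-2.03 ± 0.40), Tnc (-2.03 ± 0.37, adjusted p = 0.00215), Fam167b (-1.77), Trem2 (-1.72 ± 0.50) and Eln (-1.69 ± 0.36) were lower. Ifi44l was higher by at least 2.92 ± 0.11, at an intensity of 184.8 ± 26.6 (SD, n = 4) against 8.70 in WT lungs (5 of 5 at the floor), and so were the carboxylesterase Ces1f (1.71), Nppa (1.59 ± 0.36), the interferon gene Ifna2 (1.53), Thrsp (1.52), the glutathione transferase Gsta2 (1.42), the heart gene Tecrl (1.42) and Cox8b (1.40). In all, 1270 genes passed, 590 higher and 680 lower, with 39 and 138 by at least 1 on the log2 scale. Whether they passed or not, 1324 genes showed no overlap, 10.98% of those tested against 1.59% by chance. Without FP-KO Day 14 No. 2, 392 passed, 192 higher and 200 lower, of which 382 were among the 1270, and Trem2, Ces1f, Ifna2 and Thrsp no longer passed. The count was 740 and 804 without WT Day 14 No. 2 and No. 3. Within the sets of Day 14 samples 1147 genes passed for WT No. 1 to 3 against FP-KO No. 1 and 2, and 2 for WT No. 4 and 5 against FP-KO No. 3 and 4. As FP-KO Day 14 No. 2 is 1 of the 2 FP-KO mice of the first set, values within that set carry this mouse. They are not a separate check from leaving it out. With a common median 767 passed, 217 higher and 550 lower, so that 28.3% were higher against 46.5% with quantile normalization.

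Collagen genes were lower in 9 of 16 in FP-KO lungs at Day 14 (10 adjusted over the list alone), with Col1a1 at -1.21 ± 0.23 (adjusted p = 0.00324) and Col5a2 at -1.03 ± 0.21. Other matrix genes were lower in 13 of 19 (17 adjusted over the list alone), including Timp1 (-1.60 ± 0.26) and the fibroblast-secreted Cthrc1 (-1.24 ± 0.20). Camera gave adjusted p = 4.7e-07 and 2.49e-13, and adjusted p = 0.111 and adjusted p = 0.0839 with an estimated correlation. Per mouse the collagen mean was 10.8 ± 0.28 (SD, n = 4) in FP-KO and 11.34 ± 0.17 (SD, n = 5) in WT lungs, without overlap (exact permutation p = 0.00794, two-sided, adjusted p = 0.0604). Within the sets of Day 14 samples the collagen difference was -0.65 and -0.37, and without FP-KO Day 14 No. 2 it was -0.42. Proteases were lower in 5 of 12 (1 up and 9 down adjusted over the list alone), such as the membrane-bound Mmp14 (-1.16 ± 0.16). The protease difference was -0.95 and -0.42 within the sets, and -0.42 without FP-KO Day 14 No. 2 in place of -0.70. TGF-beta genes were lower in 3 of 12 (4 adjusted over the list alone), with Pmepa1 at -0.64. Of 11 contractile genes 1 was lower, the tropomyosin Tpm2 (-0.42), as adjusted over the list alone. The contractile difference per mouse was -0.15, and -0.26 without FP-KO Day 14 No. 2. Cell cycle genes were lower in 21 of 26 (24 adjusted over the list alone), with Cdk1 at -1.41 ± 0.30 and Plk1 at -1.25. Their mean per mouse was 8.41 ± 0.38 (SD, n = 4) in FP-KO against 9.32 ± 0.12 (SD, n = 5) in WT lungs, and the difference within the sets was -1.02 and -0.77.

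Macrophage markers were lower in 10 and higher in 1 of 18 (15 and 1 adjusted over the list alone) in FP-KO lungs at Day 14, for example C1qb (-1.10) and the Fc receptor Fcgr1 (-1.01). Interferon-stimulated genes were lower in 6 of 17 (8 adjusted over the list alone), with Cxcl10 at -1.21 ± 0.25, and cytokines in 7 of 20 (13 adjusted over the list alone), with Ccl7 at -1.38 and Il6 at -1.35. Prostanoid genes were lower in 4 and higher in 2 of 19 (6 and 3 adjusted over the list alone), with the deleted gene Ptgfr among the lower ones. With Ptgfr left out, the mean of the list per mouse differed by -0.21 (exact permutation p = 0.00794, adjusted p = 0.0604). It did not pass after adjustment, although this exact p is the smallest the test can give at Day 14. The prostaglandin E2 receptors Ptger3 (-1.18 ± 0.21), which lies 5.77 Mb from Ptgfr, and Ptger4 (-0.69 ± 0.14) were lower and the degrading enzyme Hpgd higher (0.45). Acute-phase genes (2 of 9, 4 adjusted over the list alone), p53 targets (2 of 14, 4) and alternative activation genes (2 of 11, 3) were lower in part, with Serpina3n at -0.98. NK markers did not pass over all genes (0 of 8 in limma, 3 higher adjusted over the list alone), and neither did T cell markers but for the kinase Zap70, which was higher (1.65; 1 of 12, and 1 adjusted over the list alone), with 3 of the 12 positive and a median of -0.09 (mean 0.03). Within the sets of Day 14 samples the difference per mouse was -0.95 and -0.33 for macrophage markers, -0.84 and -0.10 for alternative activation, -0.38 and 0.01 for dendritic cell, -0.53 and -0.26 for interferon-stimulated and -0.69 and -0.55 for cytokine genes. The larger values of the first set also carry FP-KO Day 14 No. 2, with a macrophage mean of 9.81 against 10.86 to 10.95 in the rest of its group. Without FP-KO Day 14 No. 2 the macrophage difference per mouse was -0.38 in place of -0.66, and Trem2, Ccl7, Il6, Hpgd and Zap70 no longer passed.

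Ciliated cell markers were higher in 8 of 12 in FP-KO lungs at Day 14 (10 adjusted over the list alone), with Dynlrb2 at 0.60 ± 0.09 and Tekt1 at 0.60. Camera gave adjusted p = 2.65e-08, and adjusted p = 0.0839 with an estimated correlation, and the difference within the sets of Day 14 samples was 0.49 and 0.57. Club cell (4 of 12, 6 adjusted over the list alone), endothelial (6 of 22, 6) and resident fibroblast markers (3 of 9, 6) were higher, including the cytochrome Cyp2b10 (0.91), Ednrb (0.79 ± 0.15) and Inmt (0.69). Cardiac and skeletal muscle genes were higher in 9 of 12 (10 adjusted over the list alone), with the calcium channel Ryr2 at 0.86, and adipocyte markers in 3 of 7 (6 adjusted over the list alone), with Adipoq at 1.08. Within the sets the endothelial difference was 0.35 and 0.09, the club cell difference 0.31 and 0.47 and the resident fibroblast difference 0.42 and 0.19. The endothelial difference was 0.14 in place of 0.22 without FP-KO Day 14 No. 2. The muscle difference within the sets was 1.10 and 0.30, and the adipocyte difference 1.21 and 0.59. Clock genes were higher in 3 of 14 (5 adjusted over the list alone), and Gsta3 (1.20 ± 0.17) and Gstm1 (1.03) among 9 NRF2 targets (3 up and 1 down adjusted over the list alone), while Junb was lower (-0.72). Without FP-KO Day 14 No. 2, 42 of the 87 genes considered by name in this comparison no longer passed, Adipoq among them. Camera's preset correlation called 19 lists, 7 up and 12 down, whereas with an estimated correlation it called 0 and 12 at an unadjusted p under 0.05. Over the 3 days 28 of 99 list means per mouse differed at an exact permutation p under 0.05, 23 of them at Day 14, and 0 did after adjustment. The smallest adjusted p, 0.0604, belongs to Day 14 lists at p = 0.00794 in the exact permutation test, the smallest it can give there. The adjusted result is thus limited by the number of mice and cannot speak against a difference.

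**Figure D3:**
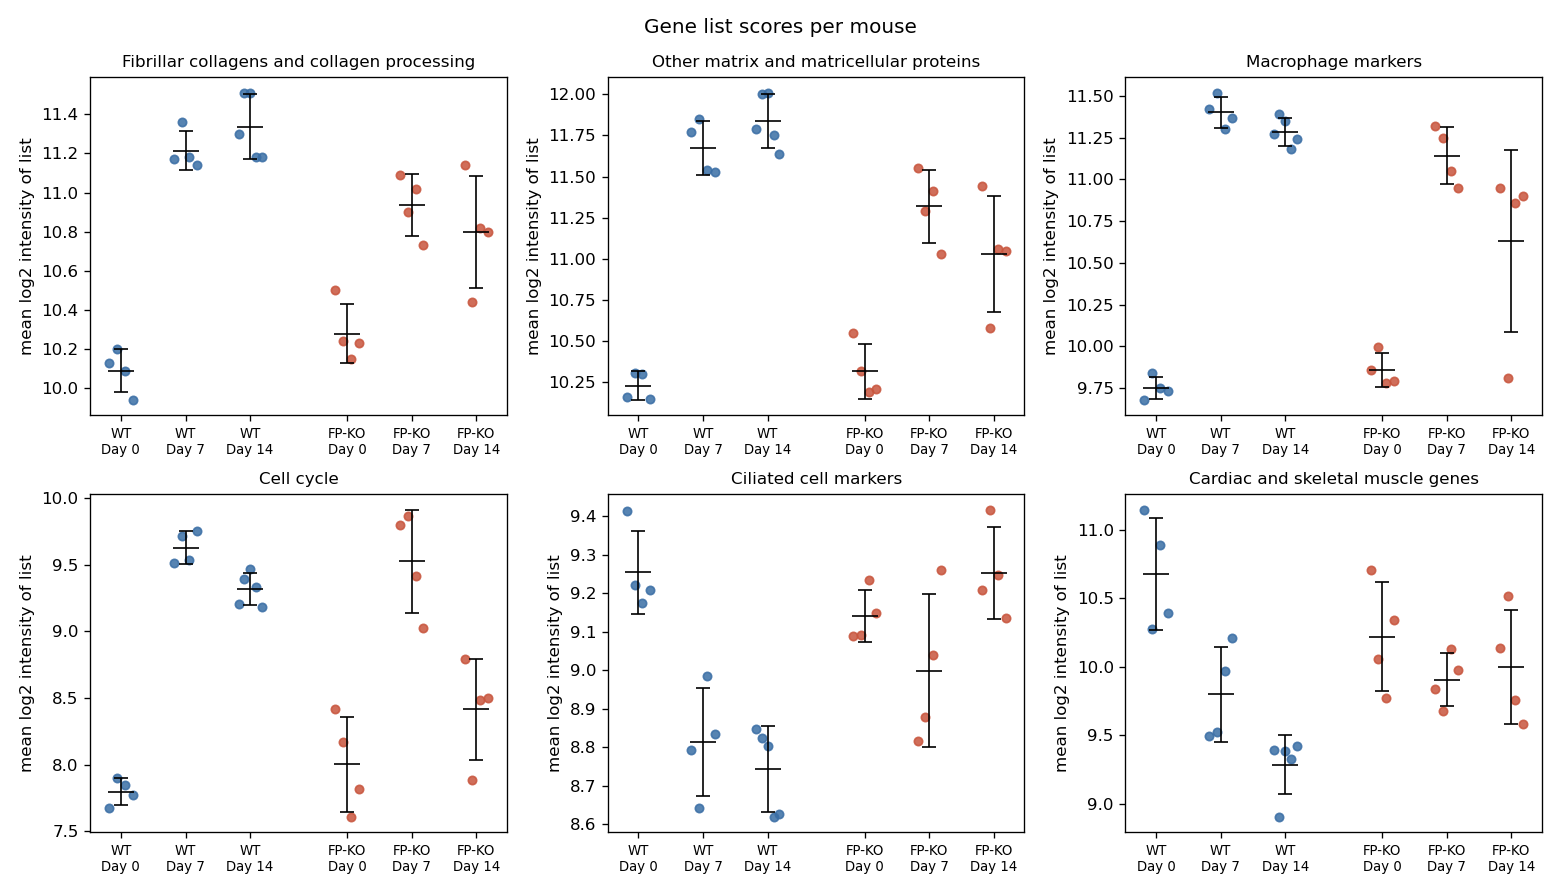
Mean log2 intensity (vertical) of 6 gene lists in each mouse of the 6 groups, with bars for the group mean ± SD. At Day 14 collagens are at 10.8 in FP-KO and 11.34 in WT lungs and cell cycle genes at 8.41 and 9.32, while ciliated markers are at 9.25 and 8.74 and muscle genes are higher by 0.71 in FP-KO lungs.

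The series design text names the comparison of time-dependent changes between genotypes, tested here as an interaction. At Day 7 the Ptgfr interaction was 0.91 ± 0.34 (adjusted p = 0.772). The smallest p values belonged to Ifi44l (0.88 ± 0.16, adjusted p = 0.126), the growth factor carrier Fgfbp1 (1.01 ± 0.22), Ccn2 (-0.88 ± 0.20), the methyltransferase subunit Wdr4 (-0.52 ± 0.12) and the dynein chain Dnah8 (1.16 ± 0.27). The Ifi44l value is neither exact nor a bound, as WT arrays were at the floor on both days (3 of 4 on Day 0 and 2 of 4 on Day 7). In limma 0 genes passed and 765 had an unadjusted p under 0.05, and with trend and robust settings 0 passed. Without WT Day 7 No. 3, 1 gene passed, as 1 did without FP-KO Day 14 No. 2. The mean collagen interaction of -0.47 holds a difference between genotypes of 0.19 at Day 0 and of -0.28 at Day 7. Of the collagen genes 4 of 16 had a lower change in FP-KO lungs adjusted over the list alone, with camera at adjusted p = 3.98e-08, and adjusted p = 0.281 with an estimated correlation. Camera's preset correlation called 16 lists, 4 up and 12 down, whereas with an estimated correlation it called 0 and 4 at an unadjusted p under 0.05.

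At Day 14 the Ptgfr interaction was 0.37 ± 0.33 (adjusted p = 0.609), and 375 genes passed, 153 with a positive and 222 with a negative value (50 and 111 by at least 1 on the log2 scale). Chl1 (-2.49 ± 0.51), Tnc (-2.28 ± 0.53, adjusted p = 0.0255), Thbs4 (-2.26 ± 0.47), Slfn9 (-2.12), the kinetochore gene Nuf2 (-2.09), the mitotic kinase Aurkb (-2.01 ± 0.44), Wfdc17 (-1.99) and Timp1 (-1.97 ± 0.38) had negative values, a lower change in FP-KO than in WT lungs. Nppa (2.24), Cox8b (2.19), the cytochrome Cyp2e1 (2.14), Mb (2.04), Adipoq (1.97), the muscle protein Smpx (1.89), the carbonic anhydrase Car3 (1.77) and Gsta2 (1.75) had positive values. Without FP-KO Day 14 No. 2, 124 genes passed, 52 positive and 72 negative, 123 of them among the 375. Of the 53 genes considered by name in this comparison 22 no longer passed without that mouse, Slfn9, Nppa, Adipoq and Car3 among them. The count also depended on other mice: 137 and 218 without WT Day 0 No. 1 and No. 4, 156, 167, 220 and 575 without WT Day 14 No. 2, 3, 4 and 5, 178, 137 and 209 without FP-KO Day 0 No. 1, 2 and 4, and 611 without FP-KO Day 14 No. 1. Within the sets of Day 14 samples 654 genes passed with WT No. 1 to 3 and FP-KO No. 1 and 2, and 0 with WT No. 4 and 5 and FP-KO No. 3 and 4, where 1257 had an unadjusted p under 0.05 in limma.

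Cell cycle genes had a lower change in FP-KO lungs by Day 14 in 14 of 26 (19 adjusted over the list alone), with Cdk1 at -1.82 ± 0.43 and Mki67 at -1.62. Collagen (8 of 16, 11 adjusted over the list alone) and other matrix genes (8 of 19, 15) did so too, with Col1a1 at -1.68 ± 0.34 and Col5a2 at -1.25. Camera gave these 3 lists adjusted p = 8.97e-18, 8.07e-09 and 1.03e-12, and adjusted p = 0.0643 with an estimated correlation for each. Macrophage markers (5 of 18, 11 adjusted over the list alone) and interferon-stimulated genes (5 of 17, 11) also had negative values, including C1qb (-1.46) and Cxcl10 (-1.59), as did Ptger4 (-0.93). Muscle genes (9 of 12, 10 adjusted over the list alone), ciliated (4 of 12, 9) and adipocyte markers (3 of 7, 6) had positive values, with the sarcolipin gene Sln at 1.48 and Dynlrb2 at 0.75. Camera gave the muscle list adjusted p = 4.48e-12, and adjusted p = 0.0643 with an estimated correlation. Gsta3 (1.32) and Cyp2b10 (1.13) had positive values. Camera's preset correlation called 19 lists, 7 up and 12 down, whereas with an estimated correlation it called 0 and 13 at an unadjusted p under 0.05.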

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

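The tests of the wider Ptgfr region over 3 days, with and without Ifi44l, of a general interferon response, of swapped arrays, of blood cell lists in FP-KO Day 14 No. 2 and of single arrays, sets of samples, scaling or fat and muscle tissue behind the weaker Day 14 change were chosen after the result was seen, whereas the other splits of the mice and the Day 0 region test were set before.

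FP-KO Day 14 No. 2 lay far from the other mice of its group in 5 measures: the macrophage mean (9.81), the alternative activation mean (8.97), the interferon-stimulated mean (9.08), the Actb 3′ to 5′ ratio (1.56) and 18S ribosomal RNA (6339). A swap with a WT mouse is excluded by its Ptgfr intensity of 33.74 against 127.3 in the lowest WT array. An exchange with a Day 0 array is excluded by the first principal component, where the highest Day 0 array lies at -24.8 and the lowest of the other FP-KO Day 14 arrays at -5.36. This does not cover a Day 0 array labelled Day 14 without exchange. On the second component this array lies at 30.0 and the Day 0 arrays between -7.97 and -2.48. Open are a mouse that may have received or answered to less bleomycin and RNA quality, since 18S and the Actb ratio are both high, although FP-KO Day 0 No. 1 lies with its group at -25.4 with 18S at 6648 and a ratio of 1.55, and Day 0 arrays run from 1.32 to 1.62 in that ratio. This array's neutrophil (-1.28), NK (-0.94), B cell (-0.63) and T cell (-0.62) means lay below FP-KO Day 0, as in its whole group. Macrophage (-0.05) and cell cycle means (-0.11) did not rise, unlike the group's (0.77 and 0.41), but other matrix did (0.26). A lung at Day 0 levels thus stays open. No other biological explanation was tested for this array, as the design gives it no group of its own, and without it the Day 14 genotype count is 392 in place of 1270.

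The Day 14 interaction passed in 375 genes, which differ between genotypes in their change from Day 0. The largest positive values were in Nppa (2.24), Cox8b (2.19), Cyp2e1 (2.14), Mb (2.04), Adipoq (1.97), Smpx (1.89), Car3 (1.77) and Gsta2 (1.75), and the largest negative ones in Chl1 (-2.49), Tnc (-2.28), Thbs4 (-2.26), Slfn9 (-2.12), Nuf2 (-2.09), Aurkb (-2.01), Wfdc17 (-1.99) and Timp1 (-1.97). Of 100 splits of the mice 1, the real one, called as many genes and the highest other called 152. These splits treat the Day 14 mice as alike although they fall into sets, so the share alone does not exclude chance. The real count was 124 without FP-KO Day 14 No. 2 and 137 without WT Day 0 No. 1, both below 152. No splits were fitted without these mice or within the sets of Day 14 samples, so chance is not excluded there either.

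The smaller change of FP-KO lungs at Day 14, a slope of 0.429 on the WT change, was weighed against 4 technical causes. The single array FP-KO Day 14 No. 2 is excluded as the whole cause, because without it the upper bound of the interval is 0.623, below 1. The sets of Day 14 samples are excluded as the whole cause by slopes of at most 0.506 within each, and scaling by slopes of at most 0.422 under the other scalings. A larger share of fat and muscle tissue in these samples, whose genes move with the pattern, would lower lung genes together if it diluted them evenly. Ciliated cell markers were higher by a mean of 0.51 (SD over genes 0.14), and cell cycle genes differed by a mean of -0.90 (SD over genes 0.34). This excludes an even dilution as the whole cause. It cannot decide on samples that hold more airway as well as fat and muscle, as club cell markers were also higher (0.36 per mouse). Fat and muscle as a part, or together with airway, stay open, as does uneven delivery of bleomycin, which may differ between mice. The loss of FP, the difference the design names, stays open too. Its effect on the Day 14 response is a hypothesis, found and tested on the same mice. Differences between genotypes at Day 0, given below for list means, also enter the slope and were not weighed.

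Ifi44l was higher in FP-KO lungs on each of the 3 days. A general interferon response is excluded as its cause at Day 14, where the median of the 17 other interferon-stimulated genes was -0.39 while Ifi44l was higher by at least 2.92, but stays open at Day 0 and Day 7, where these medians were 0.36 and 0.13 and Ifi44l was higher by at least 3.07 and 3.95. Flanking DNA of another strain around Ptgfr fits the region test over the mean of the 3 days, in which 12 of 86 genes within 20 Mb other than Ifi44l passed against 126 of 11974 elsewhere (Fisher's exact p = 2.31e-10, and 1.77e-11 with Ifi44l counted). The region test at Day 0 decides nothing, since the 1 gene of 87 that passed there is Ifi44l itself, with 0 of 11974 elsewhere in limma (Fisher's exact p = 0.00721; 403 genes had an unadjusted p under 0.05). Against a variant that changes the binding of a single probe set stands a second Ifi44l probe set, higher by at least 3.11, 4.14 and 2.78, while the last one is at or near the floor in both genotypes (0.03, 0.17 and 0.14), so that a variant under both of the former, whose probe sequences are not in the sources used here, stays open, as does an effect of FP loss itself.

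Other splits of the same mice were fitted for each comparison, and the real split is counted in. For WT, 1 of 35 splits at Day 7 called 4238 genes or more (highest other 2) and 1 of 100 at Day 14 called 4664 (highest other 4285, a split that sets WT Day 14 No. 5 with the Day 0 mice). For FP-KO, 1 of 35 at Day 7 called 2813 (highest other 93) and 1 of 35 at Day 14 called 393 (highest other 117). With all mice kept, chance is excluded for the Day 7 comparisons of both genotypes. The Day 14 splits do not keep to the sets of Day 14 samples, so their shares alone do not exclude it. Between genotypes at Day 14, 3 of 100 splits called 1270 or more, a share under the limit of 0.05 set beforehand. Another split called 1169. These splits treat the Day 14 mice as alike although they fall into sets, so the share alone does not exclude chance. The highest other, 2356, sets WT No. 4 and 5 and FP-KO No. 3 and 4 against the rest, a structure of the samples. With a block for these sets 1510 genes passed. That block also parted Day 0 and Day 7 mice No. 1 and 2 from No. 3 and 4, with 1 shift for all days. It is therefore not an adjustment for the Day 14 sets alone. Within the sets 1147 and 2 genes passed. These real counts fall as low as 101 in FP-KO at Day 14 (without FP-KO Day 14 No. 1) and 392 between genotypes at Day 14 (without FP-KO Day 14 No. 2), for which no splits were fitted. At Day 0, 3 of 35 splits called 2 genes or more and at Day 7 2 of 35 did, so chance is not excluded by the counts alone. The highest other was 132 on both days, from the split of mice No. 1 and 2 of both genotypes against No. 3 and 4, a structure that runs along the mouse numbers. With the mouse number as a block 3 genes passed at Day 0 and 2 at Day 7, and of the 8 splits that part every number pair, as the real one does, the highest other called 0. The Day 7 interaction gave 0 genes in limma (765 at an unadjusted p under 0.05), which all 100 splits reach by definition (highest other 18). This comparison decides nothing, and chance is not excluded.

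List means also differed between genotypes in their change from Day 0 by camera with the preset correlation, and 0 lists passed with an estimated one (4 at Day 7 and 13 at Day 14 at an unadjusted p under 0.05). The mean interaction at Day 7 and Day 14 was -0.47 and -0.73 for collagens, -0.45 and -0.90 for other matrix, -0.45 and -0.87 for proteases, -0.26 and -0.36 for TGF-beta, -0.17 and -0.26 for p53 targets and -0.31 and -1.11 for the cell cycle. For macrophage markers it was -0.37 and -0.76, for alternative activation -0.34 and -0.58, for dendritic cell genes -0.19 and -0.40, for interferon-stimulated genes -0.22 and -0.75, for cytokines -0.41 and -0.75 and for acute-phase genes -0.22 and -0.55. It was positive for club (0.18 and 0.44), ciliated (0.30 and 0.62), adipocyte (0.91 and 1.497) and muscle genes (0.56 and 1.17). At Day 14 alone endothelial (0.18), resident fibroblast (0.32) and clock genes (0.30) were past the threshold. These values also hold the difference at Day 0, where the mean was 0.19 for collagens, 0.20 for the cell cycle, 0.34 for interferon-stimulated genes, -0.58 for adipocyte and -0.46 for muscle genes. Dendritic cell genes differed by 0.20 at Day 0 and 0.01 at Day 7, and interferon-stimulated genes by 0.12 at Day 7. The negative Day 7 interactions of both lists thus hold no lower level in FP-KO lungs at Day 7. Without FP-KO Day 14 No. 2 the Day 14 means were -0.49 for macrophage markers and -0.23 for dendritic cell genes, and the calls of p53 targets (-0.18, adjusted p = 0.0708) and endothelial markers (0.10, adjusted p = 0.113) ended. The p53 call at Day 14 also ended without WT Day 0 No. 2, FP-KO Day 0 No. 2 or No. 3 or FP-KO Day 14 No. 3, and the endothelial call without WT Day 0 No. 3. At Day 7 the cell cycle call ended without FP-KO Day 7 No. 4 (-0.14), the cytokine call without WT Day 7 No. 2 (-0.23) and the interferon call without WT Day 0 No. 1 or WT Day 7 No. 4 (smallest mean -0.07). The Day 7 call of p53 targets ended without any 1 of 3 mice (WT Day 7 No. 1 and 2, FP-KO Day 7 No. 4), and that of dendritic cell genes without any 1 of 4 (WT Day 0 No. 1, WT Day 7 No. 2, FP-KO Day 0 No. 2, FP-KO Day 7 No. 3). For acute-phase genes 4 mice (WT Day 0 No. 1, WT Day 7 No. 4, FP-KO Day 7 No. 1 and 2), for alternative activation 5 (WT Day 0 No. 3 and 4, WT Day 7 No. 1 and 2, FP-KO Day 7 No. 4) and for club cell genes 5 (WT Day 0 No. 1 and 2, WT Day 7 No. 4, FP-KO Day 0 No. 3, FP-KO Day 7 No. 4) did so.

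Single mice lay far from the rest of their group in 15 of 246 group measures, where chance gives about 1 in 20, or 12.3. Besides FP-KO Day 14 No. 2 these were WT Day 0 No. 1 (Gapdh 3′ to 5′ ratio 0.901, 18S 2870), WT Day 0 No. 4 (log2 Ifi44l 4.73, the others at the floor) and WT Day 7 No. 1 (plasma cell mean 10.51). In WT Day 14 they were No. 1 (alveolar type 2 mean 13.42), No. 2 (muscle mean 8.90) and No. 5 (clock mean 9.72). FP-KO Day 0 No. 1 (log2 array median 7.04) and FP-KO Day 7 No. 2 (log2 array median 6.81, 18S 1112) complete them.

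Probe sets without a gene symbol in the tables used here also changed with time: of 2843 tested, 540 passed in WT at Day 7, 836 in WT at Day 14, 364 in FP-KO at Day 7 and 59 in FP-KO at Day 14.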

How the results depend on the processing

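Fits with the sets of Day 14 samples, the total least squares slope, the region test without Ifi44l, the prostanoid list without Ptgfr and list means within pairs were chosen after the data were seen. Across the alternatives set beforehand 83 of 99 gene counts stayed within 1.5 times, and of 6126 values of named genes 5746 kept direction and side of the threshold, 369 lost their call, 9 gained one and 2 reversed. Counting also each mouse left out and the added settings, 85 of 87 genes named between genotypes at Day 14 lost their call at least once. So did 52 of 53 in FP-KO at Day 14 and 52 of 53 in the Day 14 interaction. In WT 15 of 126 did at Day 7 and 39 of 131 at Day 14, and 36 of 106 in FP-KO at Day 7. The losses of 85 and of 52 are set by single fits with fewer arrays. With WT No. 4 and 5 and FP-KO No. 3 and 4 alone, 2 genes passed between genotypes at Day 14 and 0 in the interaction. With only the groups of the comparison 0 passed in FP-KO at Day 14. Such losses do not measure how far each gene depends on the settings. The Ptgfr difference between FP-KO Day 7 and Day 0, near background, reversed to -0.035 as deposited, -0.27 with the mean of probe sets, and -0.069 and -0.075 without FP-KO Day 0 No. 2 and No. 4 (range with each mouse left out -0.075 to 0.24). With a common median 166 genes passed in FP-KO at Day 14, 767 between genotypes at Day 14 and 168 in the Day 14 interaction. At Day 0 the genotype count was 4 with a higher floor and 4 with the mean of probe sets, and the Day 7 interaction gave 1 with a higher floor. Without a filter the Day 14 interaction gave 191 genes, and the correlations were 0.767 at Day 7 and 0.553 at Day 14, as dim genes enter. The stricter filter gave 0 genes in limma between genotypes at Day 0 and 0 at Day 7 (281 and 742 at an unadjusted p under 0.05), as it removes Ptgfr and Ifi44l from the genes tested, and no region test was possible at Day 0. Array weights gave 726 genes in FP-KO at Day 14, 2860 between genotypes at Day 14 and 1007 in the Day 14 interaction. The replicate block gave 590 in the Day 14 interaction and moved no other count beyond 1.5 times. Within pairs of equal number 0 list means had an exact p under 0.05 at Day 0 and 0 at Day 7 (1 and 4 unpaired), as 4 pairs cannot give less than 0.125. Camera with an estimated correlation called 0 lists in each of the 9 contrasts (3 to 15 at an unadjusted p under 0.05). With only the groups of a comparison, 0 genes passed in limma in FP-KO at Day 14 (1921 at an unadjusted p under 0.05), 500 between genotypes at Day 14 and 247 in the Day 14 interaction, with fewer arrays behind the spread. The block of sample sets, which also parts the Day 0 and Day 7 mice by number, gave 634 in FP-KO at Day 14. Without FP-KO Day 14 No. 2 this block gave 944, with 4 and 472 between genotypes at Day 7 and Day 14 and 2 and 185 in the interactions. With WT No. 1 to 3 and FP-KO No. 1 and 2 alone at Day 14, 1742 passed in FP-KO and 654 in the Day 14 interaction. With WT No. 4 and 5 and FP-KO No. 3 and 4 alone, 2484 passed in WT at Day 14, 5 and 2 between genotypes at Day 7 and Day 14, and 1 and 0 in the interactions (1257 at an unadjusted p under 0.05 for the last), with fewer arrays. With Ptgfr, the deleted gene, left out of the prostanoid list its mean no longer separated the genotypes at Day 7 (-0.06 in place of -0.16), and the region test over 3 days without Ifi44l gave 2.31e-10. Where no cause is named, the cause was not tested. Leaving out each mouse gave 3548 to 4412 genes in WT at Day 7, 3835 to 4931 at Day 14, 1866 to 3135 and 101 to 569 in FP-KO, 2 to 3, 2 to 4 and 392 to 1547 between genotypes on the 3 days, and 0 to 1 and 124 to 611 in the interactions. Lists called ran from 23 to 24, 22 to 23, 19 to 21, 14 to 22, 5 to 17, 8 to 18, 19 to 21, 12 to 18 and 18 to 19 in the same order, and list means per mouse from 0 to 0 after adjustment and 22 to 29 before. Correlations ran from 0.849 to 0.876 and 0.605 to 0.771, slopes from 0.691 to 0.810 and 0.358 to 0.502, and the region p from 2.02e-13 to 3.73e-07 over 3 days and 5.14e-05 to 0.00721 at Day 0. Differences of genes near the floor of 24.3, such as Ptgfr in FP-KO and Ifi44l in WT lungs, are limited by signal over background.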

Other observations

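Genes near Ptgfr were also read in the mean of the genotype difference over the 3 days, with adjusted p from limma. Gipc2 (-0.57, adjusted p = 0.00103), Nexn, which encodes an actin-binding protein (-0.46, adjusted p = 0.00651), St6galnac3 (-0.74, adjusted p = 0.00869), the adhesion molecule Negr1 (-0.95, adjusted p = 0.0212) and, 5.77 Mb from Ptgfr, the prostaglandin E2 receptor Ptger3 (-0.64, adjusted p = 0.0148) were lower in FP-KO lungs. St6galnac5 (0.87, adjusted p = 0.00542) and the fatty acid oxidation enzyme Acadm (0.26, adjusted p = 0.0365) were higher. These 7 of the 13 genes that passed within 20 Mb, Ptgfr not counted, were chosen after their values were seen.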
